A study of Mus musculus with 2 samples.

How the data were processed

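Total RNA from mouse hippocampus was sequenced in 2 libraries, which the labels describe as biological replicates of female B6CASTF1/J mice aged 2 months, with 300 ng of starting RNA each. They form 1 group. Per the labels, ERCC spike-in RNAs were added with a profile for stranded libraries with reduced ribosomal RNA, and the assembly is mm10. The notes that accompany the files name the M21 annotation. The authors' software is not given in the sources used here.

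For each library the authors deposited a gene table and a transcript table that, per the file headers, hold an expected count and a TPM value, in the column layout of RSEM. The same tables hold a score, the lower and upper bound of a TPM interval per gene, taken here as the authors' 95% credibility interval of that layout. A further deposited transcript table holds, per the file headers, an estimated count and a TPM value in the layout of kallisto. Its values were summed per gene and used as an alternative, called the second quantification. The expected counts imply reads of 100 bases, from length minus effective length. The second quantification held 0.003193% of the first table's counts on transcripts of 201 to 300 bases and 109% on the longest transcripts.

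All 55536 gene identifiers matched the annotation, which gave symbols, biotypes and coordinates, and 55450 of them were also in the second quantification. Entries that name no annotated gene stayed out of library sizes and tests. They were 97 spike-in sequences, which held 0.378% and 0.368% of counts in replicates 1 and 2, and 26248 numbered tRNA entries, with 4 and 6.99 counts. Annotated genes held 29490900 and 30691917 expected counts. A gene with 0 counts was given an upper limit of 3 counts.

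Expected counts were rounded to whole numbers for edgeR 4.0.16 (with limma 3.58.1 in R 4.3.3). The spread between the replicates is the square root of edgeR's common dispersion, with an intercept only, TMM factors and a low-count filter with a minimum of 10. Ratios of replicate 2 to replicate 1 used counts with 0.5 added over TMM-scaled library sizes, for genes at a mean of 1 CPM (counts scaled to a fixed library total) or more. A gene was called apart at a log2 ratio of at least 1 in size. A gene list stood apart when its median ratio lay outside the 2.5 to 97.5 percentiles of 10000 random lists of the same size, matched over 20 bins of expression. Lists with under 3 members above the minimum were not ranked. As 1 library was compared with 1 library, no p-values were computed. Detected genes had 1 TPM or more in both libraries. Levels are means ± SD over the 2 libraries. Ratios of gene pairs were taken within each library and called larger than the spread past 3 SD. Spike-in shares have exact binomial 95% intervals. Whether the libraries differ beyond sampling was checked with a chi-square over 12772 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

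The gene lists, for hippocampal fields, other cell types, neighbouring and distant tissues, receptors, hormone and stress responses, clock, imprinted, sex-linked, mitochondrial and structural RNA genes, were fixed before the data were examined, as was the rule for named genes. The rule takes the 15 protein-coding nuclear genes and 10 genes of other biotypes with the highest mean TPM at an effective length of at least 200 bases. It takes the 3 highest members of each list and any member at 0 counts in both libraries, the gene pairs and the isoform list. It also takes the 10 genes with the largest ratio in each direction among those with a mean of 1 TPM and 50 counts or more and separate intervals. Other list members named beside a list's ratio were chosen after their values were seen. The 5 further lists in the closing section were written after the ratios of the fixed lists were seen. Of the members of the 3 marker lists among them, the values of Dcn and Tac1 had been seen by then. The symbols Cyrano and Norad found no match and Rmrp matched more than 1 identifier, so these are not analysed here. Results for some further members of the lists are not given here.

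The methods were tested on simulated data. A simulated coefficient of variation of 0.1 came back as 0.0984. Of 200 genes shifted by 1.5 on the log2 scale among 15509, 97.5% were called apart, beside 8 of 15309 genes that were not shifted. Of the lists, 2 of 2 shifted by 0.3 stood apart, and 0 of 37 others did. The alternatives were DESeq2 1.42.0 size factors and dispersions, other minimums, no filter on low counts, subsets of genes, another pseudocount, means over list members, shares of TPM, the second quantification and each replicate left out. A correction of the ratios for GC content and length, and biotype shares from the second quantification, were added after the data were seen.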

Results

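The series holds total RNA sequencing of the hippocampus, the brain region that forms new declarative memories, from female B6CASTF1/J mice aged 2 months. B6CASTF1/J animals are first-generation hybrids of the C57BL/6J laboratory strain and the wild-derived CAST/EiJ strain. There were 2 libraries, each made from 300 ng of RNA, and both belong to 1 group. The labels call them biological replicates 1 and 2 and give each a tissue record of its own, but both share 1 donor record, so separate animals are not stated outright and the spread between them may be partly technical. Replicate 1 held 29490900 expected read counts on annotated genes and replicate 2 held 30691917. With 1 group there was no contrast of conditions, and the measurements are gene levels with their spread (mean ± SD, n = 2) and differences between the libraries. The labels state no further question.

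Neuronal, ubiquitous and structural genes led the profile. Among protein-coding nuclear genes the highest in the gene tables was Camk2a, the alpha subunit of the calcium and calmodulin-dependent kinase II of excitatory synapses, at 1352 ± 59.4 TPM (transcript share scaled to a fixed library total; SD, n = 2). Its gene, ENSMUSG00000024617.16, lies on chromosome 18, 60925618 to 60988152, + strand, mm10. The iron store subunit Fth1 followed at 1302 ± 42.3 TPM, the elongation factor Eef1a1 at 1260.4 ± 49.9, the cytoskeletal actin Actb at 1225 ± 6.80 and the prohormone-processing enzyme Cpe at 1029 ± 29.3 (SD, n = 2 each). The other 10 of the 15 highest protein-coding genes lay between 817 TPM (Calm3) and 1016 TPM (Aldoa). Among them were the glycolytic enzymes Aldoa and Gapdh, the hippocampal calcium sensor Hpca, the protease inhibitor Cst3, the astrocytic lipid carrier Apoe, the synaptic SNARE protein Snap25, the calmodulin genes Calm2 and Calm3, and the chaperone Hspa8. The order depends on the quantification: in the second, Gapdh (3465 and 3527 TPM in replicates 1 and 2), Actb (2666 and 2733), Eef1a1 (2377 and 2524) and Fth1 (2381 and 2459.9) lay above Camk2a (2084 and 2239).

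Non-coding RNAs reached far higher TPM than any nuclear mRNA. Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle, stood at 160870 ± 875 TPM each. Their listed counts are identical in each library, so the split of reads between these copies is uncertain. Rn7sk, the RNA that holds back transcription elongation factor P-TEFb, stood at 56504 ± 676 TPM, and the RNase P RNA Rpph1 at 6657 ± 95.7 TPM (SD, n = 2). The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 stood at 41680 ± 505 and 32869 ± 513 TPM. Malat1, a nuclear long non-coding RNA (chromosome 19, 5795690 to 5802672, - strand, mm10), stood at 6018 ± 164 TPM. Gm26917, a locus with ribosomal RNA-like sequence, reached 12075 ± 256 TPM. The labels name a profile for libraries with reduced ribosomal RNA, so levels of ribosomal and similar RNAs need not be those of the tissue. The nuclear pseudogenes Gm28661 and Gm10925 were listed at 7247 ± 413 and 6391 ± 527 TPM, values that are uncertain because they copy mitochondrial genes and share reads with them.

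**Figure D1:**
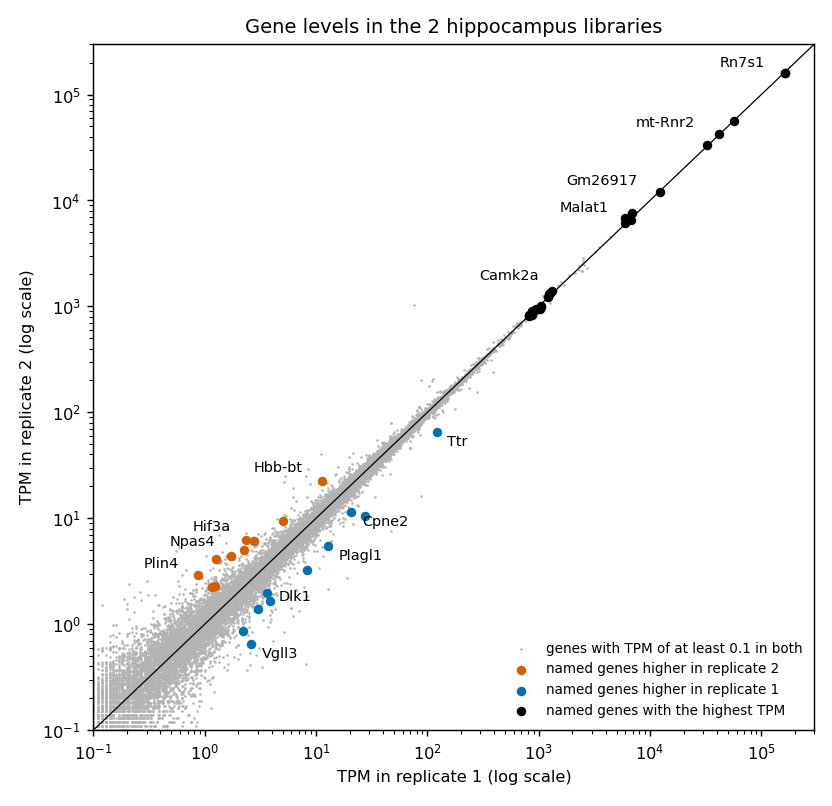
TPM of each gene in replicate 1 (x axis) against replicate 2 (y axis), both on log scales, for genes at 0.1 TPM or more in both; the line marks equal values. Black points are the genes with the highest TPM, with Rn7s1 at 160870 TPM and Camk2a at 1352, and coloured points are the 20 named genes with the largest differences between the libraries, such as Plin4 and Ttr.

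Nuclear protein-coding genes took 78.1% ± 0.121 of the expected counts (SD, n = 2). Mitochondrial ribosomal RNA took 6.62% ± 0.0899, miscellaneous RNA (mainly Rn7s1, Rn7s2 and Rn7sk) 5.73% ± 0.0354, and long intergenic non-coding RNA 5.13% ± 0.0445. Mitochondrial protein-coding genes took 1.93% ± 0.0314, ribozyme RNAs 0.147% ± 0.00304, small nuclear RNAs 0.117% ± 0.00648 and small nucleolar RNAs 0.0432% ± 0.000307. As shares of TPM, which weigh short transcripts more, miscellaneous RNA took 38.1% ± 0.251 and nuclear protein-coding genes 40.7% ± 0.104. In the second quantification, which held next to no counts on short transcripts, miscellaneous RNA took 0.000220% of counts. At 1 TPM or more in both libraries, 14903 of 55536 annotated genes were detected, among them 12786 of 22028 protein-coding genes (58.0%), 273 long intergenic non-coding RNA genes and 497 processed pseudogenes.

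The libraries differed little across genes, and by more than read sampling. The biological coefficient of variation between them was 4.86% over 17782 genes. Pearson's r of log2(TPM + 1) was 0.995 and Spearman's rho 0.940 across 55536 genes, which are not independent replicates, so no p-value is given. Over 12772 nuclear protein-coding genes the chi-square of the counts was 3.85 per degree of freedom, where sampling alone gives about 1, so the files do not hold 1 library deposited in duplicate. Synthetic ERCC spike-in RNAs took 0.378% of counts in replicate 1 (exact 95% binomial interval 0.375 to 0.380) and 0.368% in replicate 2 (0.365 to 0.370). Gene counts per spike-in count were 1.03 times as high in replicate 2. The SD of the log2 ratio between libraries was 0.10 over 28 spike-ins, against a median of 0.17 over draws of genes matched on mean count (95% of draws 0.11 to 0.39). At a minimum of 200 counts the spread of 21 spike-ins, 0.08, lay inside the range of matched genes (0.07 to 0.24). Intervals and limits given here cover counting error only.

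Markers of neurons and of every hippocampal field were present. All 12 pan-neuronal genes were detected, with a median of 264 ± 1.32 TPM (SD, n = 2), above 99.3% of protein-coding genes, led by Snap25 (851 ± 32.1), the synaptic vesicle protein Syp (688 ± 12.7) and the dendritic protein Map2 (431 ± 5.36). All 11 genes of glutamatergic neurons were detected (median 179 ± 5.37 TPM), with Nrgn at 585 ± 18.7 and the vesicular glutamate transporter Slc17a7 at 533 ± 12.4. All 15 genes of GABAergic neurons were detected (26.4 ± 2.02 TPM), led by the peptide genes Cck (261 ± 2.48) and Sst (164 ± 14.1) and by Gad1 (149 ± 1.90). Dentate gyrus granule cell genes had a median of 19.1 ± 3.56 TPM, with Calb1 at 64.5 ± 6.01, the granule cell identity factor Prox1 at 39.8 ± 5.35 and Stxbp6 at 34.5 ± 6.61. CA1 pyramidal genes had a median of 38.7 ± 1.22 TPM, with Mpped1 at 67.3 ± 1.22, Wfs1 at 57.3 ± 1.54 and Fibcd1 at 41.5 ± 2.09. For CA2, 5 of 7 genes were detected (median 5.73 ± 0.354 TPM), led by Pcp4 (102 ± 10.8), Rgs14 (42.4 ± 2.78) and Amigo2 (9.18 ± 0.693). All 6 CA3 genes were detected (13.7 ± 0.240 TPM), led by Bok (26.5 ± 1.63), Grik4 (22.2 ± 2.20) and Npy2r (16.4 ± 0.0849).

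Glial, vascular and immune genes spanned a wide range of levels. Astrocyte genes had a median of 77.4 ± 3.20 TPM (SD, n = 2), with the glutamate transporter Slc1a2 at 684 ± 27.3, Glul at 669 ± 36.5 and Aldoc at 338 ± 6.57. Mature oligodendrocyte genes had a median of 37.4 ± 3.97 TPM, with the myelin genes Mbp at 457 ± 32.6 and Mobp at 112 ± 9.35. Oligodendrocyte precursor genes stood at 10.6 ± 0.378 TPM (Tnr 58.8 ± 3.74, Olig1 36.4 ± 1.44, Pdgfra 15.3 ± 0.757). Microglial genes stood at 12.4 ± 0.488 TPM (Csf1r 27.8 ± 1.27, C1qb 20.8 ± 0.721) and endothelial genes at 13.4 ± 0.509 TPM (Slc2a1 31.5 ± 8.72, Ly6c1 24.6 ± 2.20, Cldn5 18.7 ± 3.51). Pericyte and smooth muscle genes stood at 5.01 ± 0.219 TPM (Vtn 26.8 ± 0.332, Rgs5 17.7 ± 1.47, Acta2 7.195 ± 0.06364), and leptomeningeal fibroblast genes at 5.36 ± 0.403 (Igf2 26.5 ± 0.226, Dcn 20.1 ± 5.40, Col1a2 6.08 ± 1.53). Border macrophage genes were near the minimum, with 1 of 5 detected (Mrc1 1.38 ± 0.311, Pf4 1.07 ± 0.445, Cd163 0.925 ± 0.346). Of the ependymal genes 3 of 7 were detected (Rarres2 5.99 ± 0.382, Foxj1 2.23 ± 0.106, Ccdc153 1.43 ± 0.240). Choroid plexus showed 4 of 12, with the thyroxine carrier Ttr at 93.3 ± 39.1 TPM, Kl at 4.30 ± 0.297 and Sostdc1 at 2.02 ± 0.0212. Among blood cell genes 5 of 8 were detected, with the haemoglobin genes Hbb-bs at 159.9 ± 66.0, Hba-a1 at 155 ± 62.3 and Hba-a2 at 139 ± 51.5 TPM.

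Thalamic and striatal genes were low, neocortical layer genes were higher, and genes of distant tissues were near 0. Thalamic genes had a median of 2.61 ± 0.382 TPM (Prkcd 16.1 ± 3.49, Tcf7l2 4.25 ± 0.219, Lef1 2.81 ± 0.0424), striatal genes 2.86 ± 0.0177 (Pde10a 26.6 ± 0.212, Ppp1r1b 20.6 ± 1.99, Penk 16.9 ± 0.926) and neocortical layer genes 10.1 ± 0.0495 (Fezf2 19.3 ± 4.96, Tbr1 16.04 ± 0.007071, Cux2 11.9 ± 0.269). None of the 7 cerebellum and hindbrain genes, the 8 hypothalamic and pituitary peptide genes or the 8 genes of non-brain tissues reached 1 TPM in both libraries. The highest of these lists were Pcp2 (1.06 ± 0.509), Fat2 (0.180 ± 0.0849) and Gabra6 (0.175 ± 0.0778); Pomc (0.980 ± 0.467), Avp (0.70 ± 0.45) and Trh (0.455 ± 0.0919); and Sftpc (1.21 ± 0.530), Myh6 (1.05 ± 0.156) and Myl2 (0.245 ± 0.00707). Hoxa5, Hoxb5, Hcrt, Gh, Ins2 and Umod had 0 counts in both libraries, which allows up to 0.102 CPM (counts scaled to a fixed library total) in replicate 1 and 0.0977 in replicate 2 (3 counts of the total).

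Sex-linked genes matched the female label in the gene tables. Xist, the RNA that silences 1 X chromosome, stood at 86.0 ± 5.53 TPM (SD, n = 2; chromosome X, 103460366 to 103483254, - strand, mm10), with Ftx at 20.15 ± 1.499 and Rlim at 19.1 ± 0.205 in the same X inactivation centre list. X-linked genes with Y homologues had a median of 61.4 ± 1.17 TPM, led by Usp9x (89.5 ± 1.77), Ddx3x (76.9 ± 3.39) and Eif2s3x (61.4 ± 1.17). Of the Y-linked genes, Kdm5d had 2 counts in replicate 1 and Uty had 1 count in replicate 2. Ddx3y, Eif2s3y, Sry, Zfy1, Zfy2 and Usp9y had 0 counts in both libraries.

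Activity, hormone and stress-response genes were readily measured. Of the immediate early genes, which neuronal activity induces, 14 of 15 were detected (median 10.7 ± 0.127 TPM; SD, n = 2), led by Jun (39.9 ± 0.679), Egr3 (36.6 ± 0.898) and Arc (33.1 ± 2.35). Glucocorticoid receptors and responsive genes had a median of 31.9 ± 3.63 TPM, with the mineralocorticoid receptor Nr3c2 at 65.7 ± 0.156, Zbtb16 at 51.9 ± 5.31 and Sgk1 at 36.5 ± 5.33. Circadian clock genes had a median of 22.1 ± 0.0354 TPM (Tef 109.6 ± 3.95, Cry2 40.4 ± 0.841, Nr1d1 37.0 ± 0.792), and heat shock genes 56.1 ± 7.33 (Hspa8 823.4 ± 12.95, Hsp90aa1 365 ± 6.62, Hsph1 130.4 ± 3.56). Only 2 of 10 interferon response genes were detected (among them Bst2 at 1.44 ± 0.134), and Ifit3 averaged 1.24 ± 0.488. Adult neurogenesis genes had a median of 2.69 ± 0.0283 TPM (Neurod1 12.9 ± 0.134, Sox4 8.32 ± 0.0283, Sox11 6.88 ± 0.177), and 2 of 6 proliferation genes were detected (Pcna 17.96 ± 0.6505, Mcm2 2.60 ± 0.438), beside Top2a at 0.995 ± 0.233.

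Imprinted genes, which can be read from only 1 parental copy, were detected for 22 of 25 members (median 13.5 ± 0.0636 TPM), led by Meg3 (1171 ± 143), Gnas (677 ± 32.9) and Rian (458 ± 31.6). Reads were not split by allele, so these levels do not show which copy was read. All 10 measured long non-coding RNAs were detected (median 119.9 ± 2.64 TPM), with Snhg14 at 662 ± 27.3 after Malat1 and Meg3. Of 9 measured small structural RNAs 8 were detected (median 103 ± 20.1 TPM), and Rny3 had 0 counts in both libraries. Of the genes with ribosomal RNA-like sequence, Gm42418 stood at 2092 ± 16.5 TPM and Lars2 at 24.4 ± 6.41, while AY036118 had 0 counts in both. All 13 mitochondrially encoded mRNAs were detected (median 2274 ± 41.7 TPM), led by mt-Co1 (6000 ± 171), mt-Cytb (3563 ± 133) and mt-Nd1 (3234 ± 27.7). Replication-dependent histone genes had a median of 19.6 ± 0.0813 TPM (Hist1h4h 123 ± 10.2, Hist1h4i 28.8 ± 1.16, Hist1h1c 24.4 ± 1.87), and cytosolic ribosomal protein genes 147 ± 5.44 TPM (Rps14 302 ± 2.92, Rpl4 239.8 ± 5.70, Rpl3 217 ± 0.933). Reads of histone and ribosomal protein genes can be shared with near-identical copies, so their single values are uncertain.

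**Figure D2:**
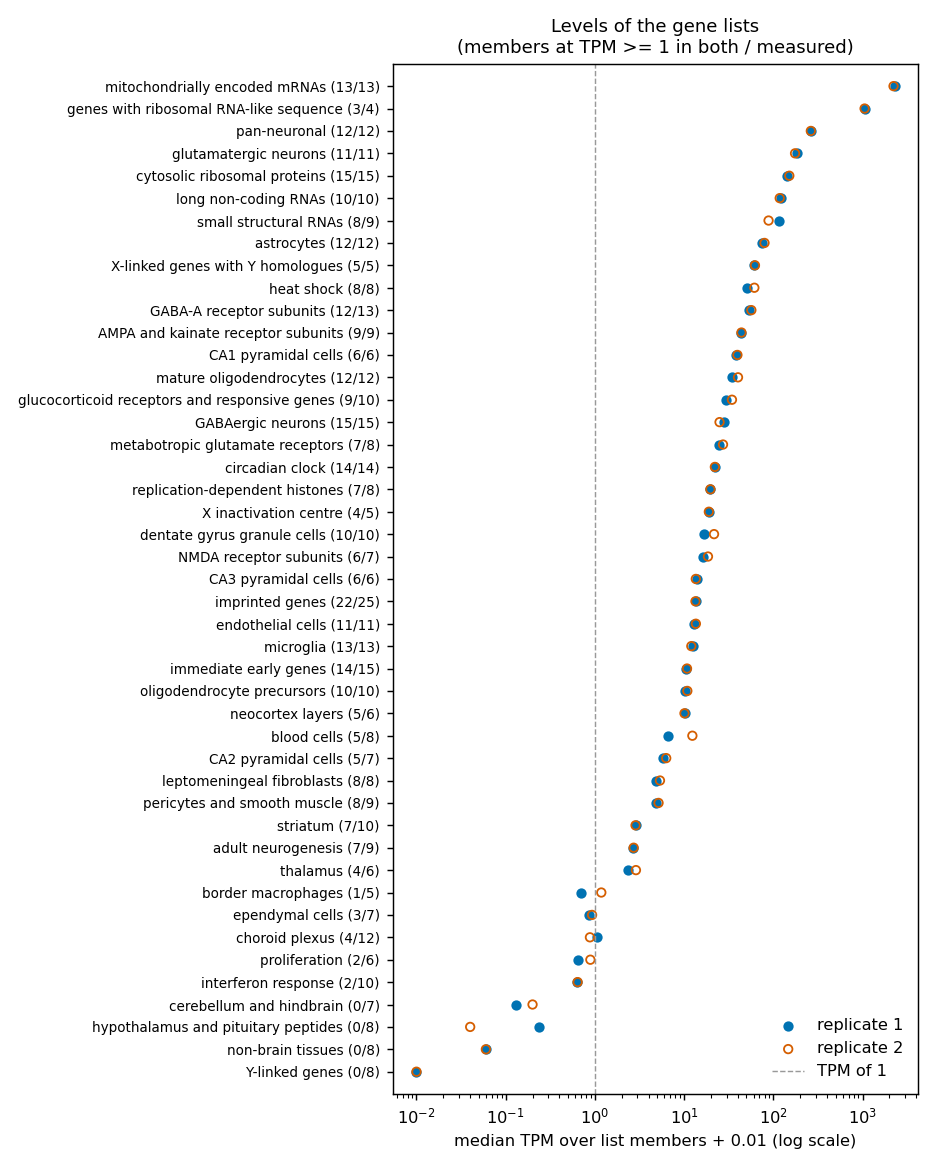
Median TPM over the members of each gene list (x axis, log scale, 0.01 added) in replicate 1 (filled) and replicate 2 (open), with the members at 1 TPM or more in both and the members measured in brackets; the dashed line marks 1 TPM. The median of the pan-neuronal genes was 264 TPM, and that of the Y-linked genes was 0.

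Ratios between receptor and transporter genes were taken within each library. Slc17a7 exceeded Slc17a6, the vesicular glutamate transporter typical of subcortical neurons, by 6.88 ± 0.38 on the log2 scale (SD, n = 2), or 118-fold, with 6.61 in replicate 1 and 7.15 in replicate 2. Among AMPA and kainate receptor subunits (median 43.5 ± 0.629 TPM, 9 of 9 detected), Gria1 and Gria2 stood at 289 ± 5.55 and 284 ± 7.16 TPM. Their log2 ratio, Gria2 over Gria1, was -0.03 ± 0.01 and did not exceed 3 SD, while Gria3 over Gria1 was -2.06 ± 0.05, so Gria1 was 4.17 times as high; Grik5 stood at 97.8 ± 1.68. Among NMDA receptor subunits (17.5 ± 1.44 TPM, 6 of 7 detected) the log2 ratio of Grin1 to Grin2a was 0.23 ± 0.15, within 3 SD. Grin2b over Grin2a was -0.09 in both libraries, past 3 SD only because the SD came to 0.0001794; an SD from 2 values can be that small by chance. Of the metabotropic glutamate receptors 7 of 8 were detected (26.2 ± 1.74 TPM), led by Grm5 (101 ± 1.57), Grm7 (32.0 ± 0.0566) and Grm2 (29.2 ± 4.16). Of the GABA-A subunits 12 of 13 were detected (55.3 ± 2.44 TPM), with Gabra5 at 74.9 ± 1.10. The log2 ratio of Gad1 to Slc17a7 was -1.84 ± 0.05, the mineralocorticoid receptor Nr3c2 over the glucocorticoid receptor Nr3c1 was 1.13 ± 0.03, or 2.19-fold, and Gfap over the water channel Aqp4 was 1.54 ± 0.02. The size of these ratios passed 3 SD for most of these pairs, and in the second quantification Gria2 over Gria1, at -0.15, did too. Ratios between genes in TPM also carry each gene's length estimate, and no test was run because an exact permutation test on so few libraries cannot reach 0.05.

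**Figure D3:**
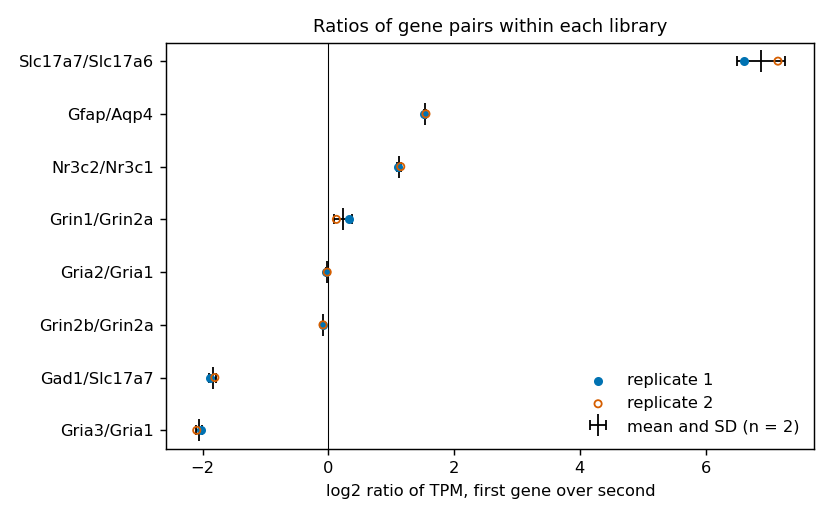
Log2 ratio of TPM within each library (x axis) for 8 gene pairs, with replicate 1 filled, replicate 2 open, and the mean and SD in black (n = 2). Slc17a7 over Slc17a6 was highest at 6.88 and Gria3 over Gria1 lowest at -2.06.

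In the first quantification the same annotated transcript was the most abundant in both libraries for all 25 genes examined for isoforms. In the second quantification this held for 24 of them. App, the amyloid precursor gene, was carried by ENSMUST00000005406.11 at 90.4% ± 0.199 of the gene's TPM (SD, n = 2), Snap25 by ENSMUST00000028727.10 at 88.5% ± 1.02 and Camk2b by ENSMUST00000109813.8 at 85.3% ± 1.88. For Camk2a, ENSMUST00000102888.9 took 64.9% ± 1.40, the Mapt (tau) transcript ENSMUST00000106992.9 66.2% ± 0.556 and the Mbp (myelin) transcript ENSMUST00000133193.8 67.4% ± 1.65. Of the AMPA subunits, Gria1 had ENSMUST00000036315.15 at 57.6% ± 1.20, Gria2 had ENSMUST00000107745.7 at 49.6% ± 2.03, Gria3 had ENSMUST00000076349.11 at 53.4% ± 0.0962 and Gria4 had ENSMUST00000163309.1 at 46.7% ± 1.08. The Bdnf (neurotrophin) transcript ENSMUST00000111045.8 took 44.5% ± 4.22, the Ntrk2 transcript ENSMUST00000109838.9 32.5% ± 0.592 and the presynaptic Nrxn3 transcript ENSMUST00000163134.7 33.6% ± 0.0535. The leading transcripts of Homer1 and Clta took 29.0% ± 1.33 and 74.0% ± 4.11. A separate transcript quantification by the authors gave the same leading transcript for 24 of the 25 genes, and shares of expected counts in place of TPM gave it for 21. The exception was Grin1, where ENSMUST00000028335.12 led in the first (35.2% ± 0.272) and ENSMUST00000114312.1 in the second (28.0% ± 0.877). Shares differed most for Mbp and for Dlg4, a postsynaptic scaffold gene, whose leading transcripts took 34.0% ± 0.960 and 27.6% ± 1.18 in the second quantification, against 58.9% ± 1.09 for Dlg4 in the first.

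Between the libraries, genes of dentate granule cells, glucocorticoid response and blood were higher in replicate 2, and imprinted and choroid plexus genes were higher in replicate 1. Of 39 lists ranked against random lists of matched expression, 15 stood outside the central 95%, 11 higher in replicate 2 and 4 in replicate 1. About 1.95 would be outside for lists of randomly drawn genes. Members of a list can vary together, and some lists share members such as Per1, so the excess over 1.95 is not a test. Each comparison is of 1 library with 1 library, with no replicate check, and the percentiles describe these libraries only. The 10 dentate granule genes had a median log2 ratio of replicate 2 to replicate 1 of 0.30 (percentile 100 of random lists), 9 of them higher in replicate 2, among them the brush border lactase gene Lct (0.48), Plk5 (0.42) and Prox1 (0.22). All 10 glucocorticoid genes were higher in replicate 2, with a median of 0.26 (percentile 100). The lipid droplet gene Plin4 had a ratio of 1.74, the cell cycle inhibitor Cdkn1a 0.68, the anti-inflammatory mediator Tsc22d3 0.50 and the receptors Nr3c1 and Nr3c2 0.01 and 0.05. Blood cell genes had a median ratio of 0.78 (percentile 100, 6 of 6 higher in replicate 2), with Hbb-bs at 0.87 and Hba-a1 at 0.80. Several of these are haemoglobin genes of the same cells, whose near-identical copies can share reads, so the 6 members are not independent. Border macrophage genes had a median of 0.81 (percentile 99.98, 3 of 3 higher in replicate 2), with F13a1 at 1.04 and the scavenger receptor gene Cd163 at 0.81.

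Shifts towards replicate 2 were also seen for mature oligodendrocytes (median 0.10, 11 of 12 members), astrocytes (0.07, 10 of 12), heat shock genes (0.11, 7 of 8), circadian clock genes (0.06, 11 of 14), CA2 genes (0.17, 4 of 6), thalamic genes (0.28, 3 of 4) and proliferation genes (0.45, 4 of 4). TPM intervals separated between the libraries for none of the proliferation genes, 1 thalamic, 1 heat shock, 2 clock and 3 CA2 genes, and for 5 astrocyte and 5 oligodendrocyte genes. All of these were higher in replicate 2 except 1 of the astrocyte genes, which was lower. Imprinted genes had a median ratio of -0.13 (percentile 0), with 18 of 22 members lower in replicate 2. Among them were the zinc finger regulator Plagl1 (-1.08), the Notch ligand-like Dlk1 (-1.23), Nnat (-0.47), Zdbf2 (-0.43) and Meg3 (-0.25). All 6 choroid plexus genes tested were lower in replicate 2 (median -0.40, percentile 0; -0.25 in the second quantification), with Ttr at -0.88, but only 1 had separate intervals. GABAergic genes (-0.07, 10 of 15 lower in replicate 2, Sst -0.18) and pan-neuronal genes (-0.05, 9 of 12) were slightly lower. These last lists and the CA2 genes lay inside the random lists when means over members replaced medians. Lists inside the central 95% included CA1 (-0.02) and CA3 genes (-0.08), microglia (-0.03), endothelial cells (0.04), AMPA and kainate subunits (-0.03), NMDA subunits (0.03), GABA-A subunits (0.01) and immediate early genes (0.04). This last list stood outside with means over members or with the correction for GC content and length, and 4 of its 5 members with separate intervals were higher in replicate 2, with Npas4 at 1.39.

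**Figure D4:**
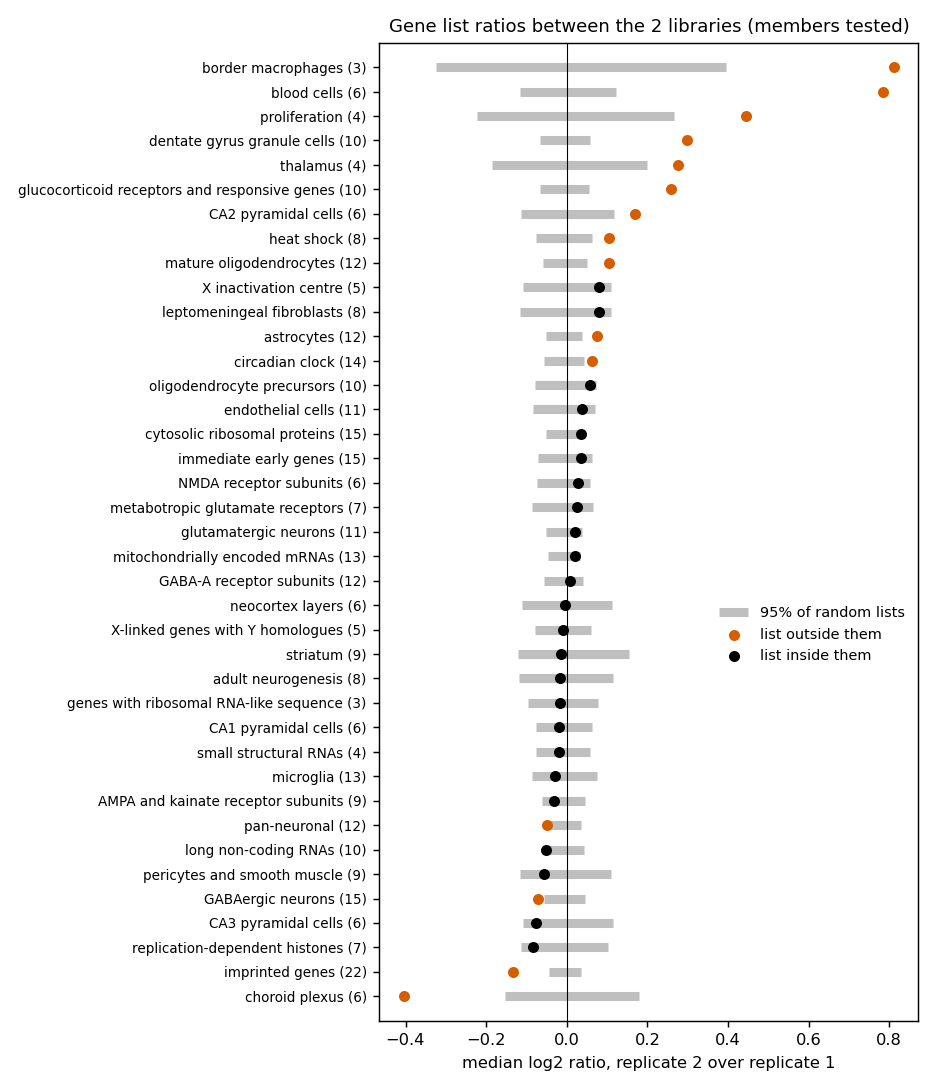
Median log2 ratio of replicate 2 to replicate 1 (x axis) for 39 gene lists, with the number of members tested in brackets; grey bars span the central 95% of 10000 random lists matched on expression. Orange points lie outside them, from border macrophages at 0.81 to choroid plexus at -0.40.

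Few single genes were far apart. Of 15509 genes at 1 CPM or more, 80 (0.516%) differed by at least 1 on the log2 scale, 41 higher in replicate 2 and 39 in replicate 1, against 3 in a draw of counts with sampling noise alone. Among the 80 were 46 protein-coding genes (0.345% of those tested) and 17 processed pseudogenes (4.93%). Pseudogenes can share reads with near-identical copies, an error that the draw leaves out. In 28 of the 80 the authors' 95% TPM intervals did not overlap, 15 higher in replicate 2 and 13 in replicate 1. These intervals need not contain the TPM printed here: for Plagl1 they ran from 13.2 to 18.3 and from 6.86 to 10.5, above its TPM in each library. Plin4 led in replicate 2 (0.870 and 2.92 TPM in replicates 1 and 2; chromosome 17, 56100591 to 56109803, - strand, mm10), followed by the activity-dependent factor Npas4 (1.73 and 4.36 TPM), the kinase gene Map3k6 (1.26 and 4.10 TPM; log2 ratio 1.37) and the hypoxia-inducible factor gene Hif3a (2.37 and 6.25 TPM; 1.33). Zbed6 (1.17), Gm15606 (1.12), Hbb-bt (0.96), Gm19439 (0.95), Gm21811 (0.88) and Rtl3 (0.88) completed the 10. Log2 ratios are of counts, while TPM also carries a length estimate, so they can differ in size, as for Map3k6 and Dlk1. In replicate 1 the transcription cofactor gene Vgll3 led (2.61 and 0.650 TPM; -2.05), followed by Gm10039 (-1.40), Dlk1 (3.65 and 1.95 TPM), the growth factor gene Hgf (-1.21), the thyroid hormone deiodinase gene Dio3 (3.87 and 1.67 TPM; -1.18), the orphan receptor gene Gpr101 (-1.12), Mid1 (-1.12), Plagl1 (12.7 and 5.49 TPM), Cpne2 (20.6 and 11.5 TPM; -0.89) and Ttr (121 and 65.7 TPM; chromosome 18, 20665280 to 20674321, + strand, mm10). Gm10039, Gm21811, Hbb-bt, Mid1 and Zbed6 are uncertain, because near-identical copies or an overlapping gene can share their reads. In the second quantification Gm15606 fell to 0.27, Gm21811 to 0.39 and Gm19439 to 0.60, and Gm10039 had 0 TPM in both libraries, so the calls for Gm15606 and Gm10039 found no support there.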

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

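The second quantification, used in the report as an alternative to the gene tables, held estimated counts on Y-linked genes in libraries labelled female, above the 3 counts that a count of 0 allows. Summed over the 8 Y-linked genes these came to 168.4 in replicate 1 and 202.5 in replicate 2. The histone demethylase gene Kdm5d held 83.6 and 108 of them and its relative Uty 70.8 and 86.4, with 53.5 and 64.3 on the retained-intron transcript Uty-212. In the gene tables the same genes held 2 expected counts in replicate 1 and 1 in replicate 2. The cause was not tested.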

How the results depend on the processing

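Of 800 values under alternatives, 612 kept their direction and their side of the threshold or stayed within the replicates' spread, 172 moved, 9 became stronger, 5 weaker and 2 reversed. Unless stated, the cause was not tested. With 2 libraries, each always lies within 1 SD of their mean. Leaving a replicate out therefore could not move a gene's TPM or a biotype share, and seldom a list median. The 50 gene TPM and 8 biotype shares that stayed were all of this kind, so 612 overstates the stability. Of the moved values, 25 were TPM of single genes, all in the second quantification, where Gapdh went from 965 to 3465 and 3527 in the 2 libraries and Gm10925 from 6391 to 2478 and 3928. The short RNA Rn7s1 fell to 0.928 and 3.27, Rn7sk to 1.62 and 0 and Rpph1 to 4.27 and 3.44. Another 95 were list medians, so TPM levels hold only for the gene tables and their total: the pan-neuronal median was 489 in the second quantification and 654 over protein-coding nuclear genes. The spread between replicates was 5.01% with no filter, 4.25% over protein-coding nuclear genes, 4.59% in the second quantification and 0.01% as the median of DESeq2's gene-wise values, which is that tool's floor. Pearson's r was 0.987 with a pseudocount of 0.1, 0.993 over genes at 1 TPM or more and 0.997 without mitochondrial and short genes. Genes apart numbered 1254 (57 with separate intervals) at 0.1 CPM or more, where sampling noise alone gave 954, and 18 (9) at 5 or more, where fewer genes were tested. As shares of TPM, nuclear protein-coding genes took 40.7%, long intergenic non-coding RNA 2.76%, mitochondrial ribosomal RNA 7.504% and miscellaneous RNA 38.1%. Without mitochondrial genes in the total, the first, second and last of these took 85.4%, 5.60% and 6.27% of counts. In the second quantification, chosen for this after the data were seen, the shares were 83.3%, 6.21%, 6.44% and 0.000220%, and spike-ins took 0.27%. Members detected, in the order second quantification, 0.5 TPM or more and TPM over protein-coding nuclear genes alone, numbered 4, 3 and 4 for border macrophages, 6, 6 and 6 for ependymal cells, 7, 7 and 8 for choroid plexus, 1, 1 and 1 for hypothalamic and pituitary peptides, 2, 2 and 2 for non-brain tissues and 5, 5 and 6 for the interferon response. For cerebellum and hindbrain the last 2 of these gave 1 and 1. The second quantification detected 2 Y-linked genes and 2 small structural RNAs. With either replicate left out, members detected ranged from 1 to 4 for border macrophages, 0 to 1 for cerebellum and hindbrain, 2 to 4 for the interferon response, 1 to 1 for hypothalamic and pituitary peptides and 1 to 1 for non-brain tissues. With means over members in place of medians, list ratios were -0.043 for pan-neuronal, -0.058 for GABAergic and 0.122 for CA2 genes, now inside the random lists. Immediate early genes (0.164) and the X inactivation centre (0.215) were then outside, and genes with ribosomal RNA-like sequence (0.165) and mitochondrial mRNAs (-0.067) reversed, as a mean gives weight to single members such as Npas4, Tsix, Lars2 and mt-Co2. In the second quantification the X inactivation centre (0.10) and mitochondrial mRNAs (0.052) stood outside, and Gria2 over Gria1 at -0.15 passed 3 SD. With ratios corrected for GC content and length, chosen after the data were seen, pan-neuronal genes (-0.040) fell inside, and oligodendrocyte precursors (0.077), immediate early genes (0.074), long non-coding RNAs (-0.061) and ribosomal proteins (0.040) outside. No paired analysis was possible because the series holds 1 group. Ratios between the replicates need both libraries, so none could be left out for them. Depth limits genes under 1 CPM, and 954 of 21450 genes crossed the limit of size in the draw of sampling noise at the lower minimum.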

Other observations

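Of 13914 genes with a mean of 1 TPM and 50 counts or more, 326 higher in replicate 2 and 322 higher in replicate 1 had separate intervals. A small selection of further genes with separate intervals, outside the fixed lists or the named-gene rule, is given here. They were chosen after their values were seen. Their log2 ratios are of counts and can differ in size from those of the TPM given. Higher in replicate 2 were Xdh, the purine-degrading xanthine dehydrogenase gene (log2 ratio 0.74, 3.48 and 7.33 TPM in replicates 1 and 2), the Notch modifier Lfng (0.54), the lipid transporter gene Mfsd2a of brain endothelium (0.46, 12.8 and 17.9 TPM), Nfkbia, an inhibitor of NF-kappa-B (0.43), and the thyroid hormone activating deiodinase gene Dio2 (0.44). Lower in replicate 2 were the collagen gene Col6a1 (-0.79, 13.3 and 7.65 TPM), the transcription factor genes Tshz2 (-0.71) and Nr2f2 (-0.56), the somatostatin receptor gene Sstr1 (-0.59) and Cpne7 (-0.47, 138 and 100.4 TPM). The tetraspanin gene Tspan10, under the minimum of 50 counts, held 65 counts in replicate 1 and 3 in replicate 2.

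All tests of explanations that follow, and the further marker lists in them, were chosen after the results were seen. They concern the make-up of the tissue and the measurement. No biological explanation was tested in the sense of a difference between groups, since the design has 1 group.

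The list of glucocorticoid receptors and responsive genes was higher in replicate 2; its tests use all 10 members, with the receptors Nr3c1 (0.01) and Nr3c2 (0.05), and the responsive genes alone were not compared. GC content and gene length are unlikely to account for this, as the list's median after correction for them was 0.27, past the 0.06 that bounds the random lists. A larger share of astrocytes, oligodendrocytes, endothelium or pericytes is also unlikely: the highest of these 4 lists, mature oligodendrocytes, stood at 0.10 against 0.26. Members of both lists were drawn anew with replacement, and the oligodendrocyte median lay below the glucocorticoid median in 97.0% of such bootstrap draws. The draws resample genes of 1 pair of libraries, not animals. Border macrophage (0.81) and blood cell (0.78) lists were higher still and were not part of that test, so their share stays open. Whether more dentate granule cells could account for the shift of the glucocorticoid list was left open. The dentate list stood at 0.30, and its median lay below the glucocorticoid median in 41.6% of draws.

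Dentate granule cell genes were higher in replicate 2. GC content and length are unlikely as a cause, with a corrected median of 0.31. More dentate gyrus in the dissected tissue was left open. The shift extended to 8 of 8 further granule cell markers, among them Pdzd2 (0.41), Maml2 (0.38) and Dock10 (0.33), with a median of 0.30. Markers of the same cells in the same libraries cannot tell a difference in dissection from another cause that raises granule cell genes.

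Imprinted genes were lower in replicate 2. GC content and length are unlikely as a cause, with a corrected median of -0.15. Mapping of CAST/EiJ alleles to the reference was left open by the test of parental origin. Medians of maternally (4 of 5 lower) and paternally expressed members (12 of 14) were -0.19 and -0.18. The maternal one rests on 1 cluster, Meg3, Rian and Mirg, beside Ube3a (-0.03) and Cdkn1c (0.19). The labels give both libraries the same hybrid strain and 1 donor record, so by the labels such mapping would act alike on both. The alleles themselves were not examined. More ventral hippocampus in replicate 1 was left open: the median of 7 ventral markers was -0.33, but Dcn (-0.57) had been seen before the list was written. More hypothalamus or amygdala in replicate 1 was left open too. Of 11 markers 6 were tested, with a median of -0.37, from Nos1 (-0.03) to Tac1 (-0.66), which had been seen. The others were under the minimum: Cartpt averaged 0.805 TPM, Irs4 0.065 and Otp 0.055, while Calcr and Sim1 had 0 TPM in both libraries. None of the 8 hypothalamic and pituitary peptide genes of the fixed list reached 1 TPM in both libraries.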
